A study of Homo sapiens with 9 samples.

How the data were processed

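The values are one table of RMA intensities for 9 Affymetrix arrays with 54675 probe sets each. Per the labels' protocols, 100 ng of total RNA per array, isolated with a PicoPure kit, was amplified with NuGEN's Ovation system and hybridised as biotinylated cDNA. The deposited values are intensities on a linear scale, with medians of 104.7 to 107.4, and were made with GCOS and RMA per the submitters' processing notes, which give no versions. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, so a change in the total RNA of a cell is not measured. Whether the 9 arrays were normalized together is not given in the sources used here. The test design had assumed log2 values. Since the values were linear, they were transformed to log2 first, with no pseudocount, all being above 0.

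Probe sets were named from the platform's annotation. Of the 54675, 62 are controls, 41091 name 1 gene, 1801 name several and 11777 are unnamed here, some of the controls among them. The gene numbers of 41043 single-gene probe sets were found in a current reference table and no symbol needed an update. For each of 19775 genes the probe set with the highest mean over all arrays was used, among those naming a single gene. Of these genes 10523 had more than 1 probe set. No genome build is named for the annotation, so no coordinates are given. Some members of the gene lists are not analysed here, since no probe set names them alone. The arrays have no read depth, and their number limits the precision. There were no missing values and no filter on low values. Probe sets for 27 bacterial poly-A controls gave the background bound of 5.29 (log2), a bound chosen after the data were seen.

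Expression was tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays, which share an estimate of the spread, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 3 comparisons were stage 1 against hESC, stage 2 against stage 1 and stage 2 against hESC. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9. The camera test of limma, with a preset correlation of 0.01 between genes, was run on 25 gene lists and adjusted over the lists of a comparison. It asks whether the genes of a list moved further in one direction than other genes. Some genes are in several lists, so the calls of those lists are not independent. CER1 is in the definitive endoderm and the Nodal and Activin lists, and NODAL in the latter and the primitive streak list. COL4A1 and LAMA1 are in the basement membrane and extraembryonic endoderm lists. The lists were pluripotency, primitive streak and mesendoderm, definitive endoderm, gut tube and foregut, liver and yolk sac secreted proteins, hindgut, extraembryonic endoderm, basement membrane, Nodal and Activin signalling, Wnt targets, Hedgehog pathway, FGF receptors and feedback, retinoid genes, epithelial, mesenchymal, cell cycle, cholesterol synthesis, hypoxia and glycolysis, dissociation stress, and reference genes, with neural, mesoderm and cardiac, endothelial and blood, trophoblast and fibroblast markers for other cell types.

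The samples' groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls of each step, and 5 and 5 for stage 2 against hESC, among genes at adjusted p under 0.05 whose groups did not overlap. It added 6 genes for each course over both steps, ranked by the smaller of their log2 changes, and the members of the lists. Probe sets of several genes, uncharacterised loci and sex-linked genes used for sex calls were left out of naming. The ranking used fitted changes, which have no order among genes at background.

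The scripts were tested on simulated arrays made from the mean of each gene over all 9 arrays and its spread within each of the 3 groups. Of 19775 genes, 50 were changed at each size and the 21 cell cycle genes lowered by 1 (log2), at stage 1 and stage 2 alike. Recovery was read from stage 1 against hESC. At a log2 change of 0.5, 58% were recovered, at 1, 90%, and at 2 and at 4, 100%. Of 19554 unchanged genes 20 were called. For stage 2 against stage 1, where no gene had been changed and every call is false, 11 of 19775 were called. Camera called 1 of 25 lists, the lowered cell cycle genes, for stage 1 against hESC and 0 for stage 2 against stage 1. Courses were set beside 20 simulations with no effect. Alternatives tried were eBayes with trend and robust spread, the mean of all probe sets of a gene, a filter on genes with a mean under the median of all values (6.73, log2; 13255 genes left), centring or quantile normalization of the arrays, array weights, a fit of the compared groups alone, the replicate number as a block, each array left out in turn, camera with an estimated correlation and fry. One more, without probe sets marked as shared between transcripts, was chosen after seeing the data.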

Results

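Transcript levels were measured on 9 microarrays in human embryonic stem cells (hESC) and in endoderm cells made from them, in 3 groups of 3 arrays. The hESC arrays come from H9, an established embryonic stem cell line. The stage 1 and stage 2 arrays come from hSOX17-2, a modified hESC line, from which cells positive for an eGFP reporter of SOX17 were purified by flow cytometry. SOX17 is a transcription factor that marks endoderm, the germ layer of gut, liver and pancreas. Stage 1 followed 1 day with 25 ng/ml Wnt3a and 100 ng/ml Activin A, then 2 days with Activin A and 0.2% fetal bovine serum. Stage 2 followed 3 more days with 2% serum, 50 ng/ml FGF10 and 0.25 µM KAAD-cyclopamine, an inhibitor of Hedgehog signalling. The labels give the arrays of a group as biological replicates. They do not say that the hESC were sorted, so the line and the sort differ together with the stage in both comparisons against hESC, and only stage 2 against stage 1 keeps the same line and sort.

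The median intensity of an array lay between 104.7 and 107.4. Arrays of one group correlated with r = 0.992 to 0.998 over probe sets on the log2 scale, and arrays of different groups with r = 0.930 to 0.957. The median standard deviation of a gene within a group was 0.07 in hESC, 0.09 at stage 1 and 0.15 at stage 2 on the log2 scale, so the stage 2 arrays varied more. Control probe sets also differed between groups. The 18S ribosomal RNA control gave 15920 ± 383 intensity in hESC, 11800 ± 1006 at stage 1 and 3058 ± 1051 at stage 2 (SD, n = 3). The beta-actin probe set at the 3' end exceeded the one at the 5' end by 2.30 ± 0.10 (log2) in hESC, 1.52 ± 0.19 at stage 1 and 2.41 ± 0.23 at stage 2. The highest of 27 bacterial poly-A control probe sets over all arrays reached 5.29 (log2), which was taken as the background. Where 1 group's mean lay under it, the change is given as a bound ("at least"). Counts of list members include 8, 6 and 4 calls, for stage 1 against hESC, stage 2 against stage 1 and stage 2 against hESC, of genes under it in both groups, for which no size is given. In the same order, 11, 27 and 17 calls of list members were lost when some single array was left out, of which those in lists that passed camera are named below. Fold changes below are on the log2 scale with the standard error of the limma fit, n = 3 arrays per group, unless a fold is named. The fit pools the spread of a gene over the 3 groups, so its standard error is the same in each comparison. Errors and p-values of a gene that varied most at stage 2 thus tend to be too small in comparisons with stage 2. For stage 1 against hESC they tend to be too large. CER1, for example, had an SD of 0.07 in hESC, 0.07 at stage 1 and 0.64 at stage 2.

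**Figure D1:**
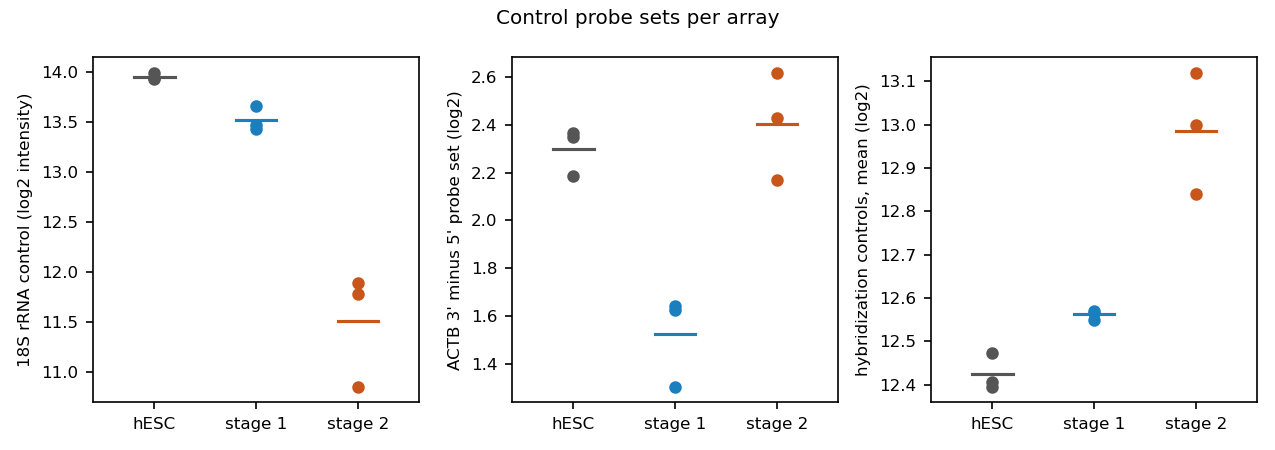
Control probe sets on each of the 9 arrays by group (points, with the group mean as a line): 18S ribosomal RNA control (log2 intensity), beta-actin 3' minus 5' probe set (log2) and the mean of the hybridization controls (log2). The axes do not start at 0. The 18S control averaged 13.96 in hESC, 13.52 at stage 1 and 11.51 at stage 2.

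The comparison of stage 1 with hESC asks what distinguishes sorted SOX17+ cells after Wnt3a and Activin A from undifferentiated cells. All 13 measured genes of the definitive endoderm list rose. SOX17 itself, on which the cells were sorted, was at least 209-fold higher, which checks the labels and is no finding. The transcription factor FOXA2 rose 64.1-fold, GATA6 rose by 7.48 ± 0.10, GATA4 rose at least 109-fold, and PRDM1, a transcriptional repressor, rose by 6.51 ± 0.17. CXCR4, a chemokine receptor used to isolate definitive endoderm, rose by 3.55 ± 0.07, and CER1, a secreted inhibitor of Nodal, BMP and Wnt signals, by 8.08 ± 0.25, a 270-fold change. The list, with SOX17 in its count and test, passed limma's camera test with adjusted p = 8.3e-12, and with adjusted p = 0.032 with an estimated correlation. It was not tested without SOX17. Adjusted over the list alone the count was also 13 of 13.

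All 21 measured cell cycle genes fell, and 12 of them at least 2-fold. MCM5 and PCNA, which act at the replication fork, changed by -2.07 ± 0.08 and -1.86 ± 0.09, and PLK1, a mitotic kinase, by -1.44 ± 0.10 (camera, adjusted p = 1.6e-08, and adjusted p = 0.036 with an estimated correlation). Adjusted over the list alone 21 fell as well. Of 9 measured genes of Nodal and Activin signalling, 8 rose, also adjusted over the list alone. CER1, given above with the definitive endoderm list, is among the 8. The mean change of the list was 2.12 and its median 0.66. NODAL, a ligand of that pathway, rose by 3.92 ± 0.07, LEFTY1, its secreted inhibitor, by 3.30 ± 0.09, and PMEPA1, a feedback inhibitor, by 1.76 ± 0.08, while SKIL changed by 0.02 ± 0.08 and did not pass the test. That list passed camera with adjusted p = 6.4e-05, and with adjusted p = 0.039 with an estimated correlation.

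Of 15 measured pluripotency genes, 9 fell and 2 rose, and adjusted over the list alone 9 fell and 3 rose. SOX2, a core pluripotency factor, fell by 5.12 ± 0.13, PRDM14 by 3.10 ± 0.18, USP44 by 2.85 ± 0.07 and DNMT3B, a DNA methyltransferase, by 2.03 ± 0.10. NANOG, another core factor, changed by -0.24 ± 0.11 (limma, adjusted p = 0.098) and LIN28A, an RNA-binding protein of stem cells, by 0.03 ± 0.07 (adjusted p = 0.79), so neither passed. SALL4 and VRTN rose by 0.40 ± 0.11 and 0.93 ± 0.09. The camera call at adjusted p = 0.028 was lost at adjusted p = 0.14 with an estimated correlation, at adjusted p = 0.061 with the filter on low values and at adjusted p = 0.092 without shared probe sets.

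Of 13 primitive streak and mesendoderm genes, which mark gastrulating cells, 7 rose and 3 fell, with the same counts adjusted over the list alone. FGF17, a secreted growth factor, rose by 6.01 ± 0.14, EOMES and GSC, transcription factors of the streak and organizer, by 5.26 ± 0.07 and 5.11 ± 0.20, and MIXL1 by 4.15 ± 0.13. The fallers were FGF4 (-3.24 ± 0.19), MESP2 (-0.38 ± 0.08) and TBXT (-0.36 ± 0.08), the gene of brachyury. Camera gave adjusted p = 0.0078, and adjusted p = 0.14 with an estimated correlation. Among 12 Wnt targets 9 rose and 2 fell, also adjusted over the list alone, with AXIN2, among the 9, losing its call without any 1 of the 6 arrays (adjusted p = 0.060 to 0.083). LGR5, a receptor for R-spondins, rose at least 66.7-fold, DKK1, a secreted Wnt inhibitor, at least 68.8-fold and SP5 at least 20.6-fold, while LEF1 fell by 2.72 ± 0.26 and ZNRF3 by 0.98 ± 0.09 (adjusted p = 0.0014, and adjusted p = 0.14 with an estimated correlation).

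Of 13 Hedgehog pathway genes 9 fell and 2 rose, as they did adjusted over the list alone. GLI1, both a transducer and a target of the pathway, fell by 2.11 ± 0.14, HHIP, a ligand-binding target, by 2.09 ± 0.11 and the receptor gene PTCH1 by 0.85 ± 0.06, while the ligand IHH rose by 0.74 ± 0.18 and GAS1 by 0.74 ± 0.12. The call of adjusted p = 0.032 was lost at adjusted p = 0.14 with an estimated correlation, at adjusted p = 0.061 with the filter on low values and at adjusted p = 0.066 with the 2 groups alone. Of 9 mesenchymal genes 7 rose and 1, ZEB2, fell within the background, a call lost without hESC replicate 2 (adjusted p = 0.055) or 3 (adjusted p = 0.050). ZEB1, a repressor of CDH1, rose at least 13.4-fold, CDH2 (N-cadherin) by 1.25 ± 0.11, and MMP14, a matrix protease, by 1.47 ± 0.10 (adjusted p = 0.0014, and adjusted p = 0.14 with an estimated correlation). CDH1 (E-cadherin), in the epithelial list, fell by 1.66 ± 0.07, while KRT8 and KRT19, epithelial keratins of the same list, rose by 1.97 ± 0.07 and 1.84 ± 0.06. Among 8 extraembryonic endoderm genes 7 rose, among them DAB2, an endocytic adaptor, by 1.51 ± 0.07 and COL4A1, a basement membrane collagen, by 1.32 ± 0.06 (adjusted p = 0.0014, and adjusted p = 0.13 with an estimated correlation). PDGFRA, another of the 7, rose by 0.79 ± 0.13 but stood at -0.26 when all its probe sets were averaged. Adjusted over the list alone, 7 extraembryonic genes rose and 1 fell, and the mesenchymal counts did not move.

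The largest rises besides SOX17, CER1 and GATA6 included those of GATA6-AS1, the antisense partner of GATA6 (at least 266-fold), ERBB4, a receptor tyrosine kinase (at least 244-fold), SLC5A9, a sugar transporter (at least 176-fold), PLSCR2 (at least 171-fold), SLC40A1, the iron exporter ferroportin (at least 148-fold), ASB5 (at least 72.8-fold) and APOA2, an apolipoprotein of the liver and yolk sac list (241-fold, 7.91 ± 0.11). The largest falls included CNMD, the gene of chondromodulin (at least 89.4-fold), JAKMIP2-AS1 (at least 70.4-fold), VAT1L (at least 56.9-fold), CUZD1 (at least 44.1-fold), PCDH8, a protocadherin (at least 38.3-fold), and TRIM22, an interferon-induced protein (at least 34.7-fold). SPP1, the gene of osteopontin, fell by 5.98 ± 0.10, NPTX2 by 5.97 ± 0.17, the long non-coding RNA MIAT by 5.70 ± 0.13 and CRYBG1 by 5.49 ± 0.22.

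Over all 19775 genes tested with limma, 4667 rose and 6206 fell at adjusted p under 0.05, of which 1457 and 2036 changed at least 2-fold. The arrays of stage 1 and hESC did not overlap for 67.8% of genes, against 10% by chance. Of 6552 called genes with several probe sets, 690 had probe sets called in opposite directions. Lists of markers of other cell types did not pass camera. Fry, which does not compare a list with other genes, called each of them. Its adjusted p was 0.0020 for the neural list, pointing up. Pointing down, it was 0.0055 for mesoderm and heart, 4.4e-07 for endothelium and blood, 0.0023 for trophoblast and 9.8e-06 for fibroblasts. Of the neural list 2 of 10 genes rose and 2 fell (camera, adjusted p = 0.95), of mesoderm and heart 1 of 10 rose and 4 fell (adjusted p = 0.64), of endothelium and blood 0 of 11 rose and 6 fell (adjusted p = 0.061), of trophoblast 3 of 9 rose and 2 fell (adjusted p = 0.92), and of fibroblasts 2 of 10 rose and 4 fell (adjusted p = 0.50). Adjusted over the list alone 3 trophoblast genes fell and the other counts held. Basement membrane had 7 rises and 3 falls among 11 genes (adjusted p = 0.061), FGF receptors and feedback 8 and 4 among 14 (adjusted p = 0.10), foregut 3 and 1 among 11 (adjusted p = 0.29), secreted liver and yolk sac proteins 3 and 5 among 14 (adjusted p = 0.99), hindgut 1 and 1 among 6 (adjusted p = 0.99) and epithelial genes 3 and 4 among 12 (adjusted p = 0.53), as they did adjusted over the list alone. Without the probe sets shared between transcripts AGRN, a basement membrane gene counted as rising, stood at -0.056 and FGFR2, counted as falling, at 0.65. Single members of these lists moved far, such as SIX3, a transcription factor of the forebrain and eye (5.47 ± 0.15), and GATA3 (4.10 ± 0.10). THY1 and COL1A2, members of the fibroblast list, fell by 3.48 ± 0.09 and 1.79 ± 0.09. The hESC were grown on mouse feeder cells, and whether the feeders added to the hESC signal of these genes was not tested.

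**Figure D2:**
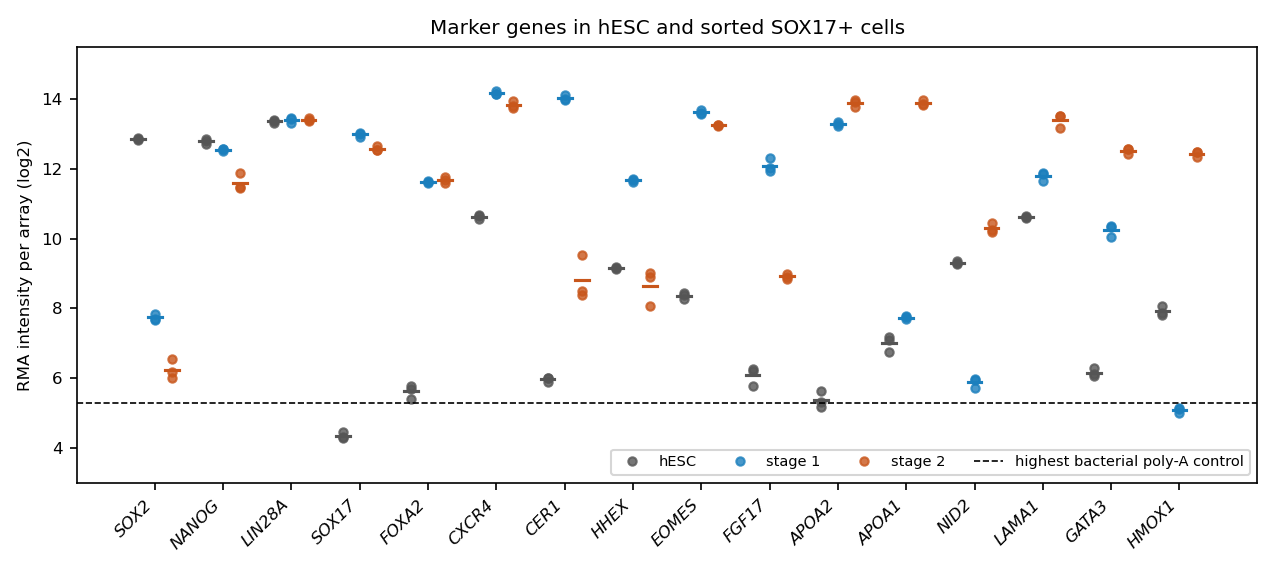
RMA intensity (log2) of 16 marker genes on each array, with points for the 3 arrays of a group and a line at its mean, and a dashed line at the background of 5.29. SOX2 falls at both steps, the endoderm genes SOX17, FOXA2 and CXCR4 stay high at both stages, CER1, HHEX and FGF17 are highest at stage 1, and APOA1 and HMOX1 are highest at stage 2.

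Stage 2 against stage 1 compares cells of the same reporter line and gate before and after the 3 days with FGF10 and KAAD-cyclopamine. Camera called 7 lists, each call being lost with an estimated correlation: secreted liver and yolk sac proteins, basement membrane and extraembryonic endoderm rose, and Nodal and Activin signalling, primitive streak, pluripotency and definitive endoderm fell. APOA1, the main protein of high-density lipoprotein, rose by 6.16 ± 0.11, a 71.5-fold change, and APOB, the protein of low-density lipoprotein, by 5.56 ± 0.24. FGA, a fibrinogen chain, rose at least 6.88-fold, TTR, a thyroid hormone carrier, by 2.01 ± 0.47 (2.67 without stage 2 replicate 2, the lowest of its group), and AFP, a fetal plasma protein, by 2.33 ± 0.25 after a fall of 3.79 ± 0.25 at stage 1. That replicate was also lowest for APOB (11.22 against 12.12 and 12.33, log2), APOC3 (7.21 against 8.41 and 8.47) and FGB (5.41 against 7.24 and 8.18). It was highest for AHSG (6.30 against 5.82 and 6.23). In all 13 of 14 measured members rose and 1, TF, fell by 0.21 ± 0.07, though TF stood at 0.08 when all its probe sets were averaged and lost its call without any 1 of 5 arrays (adjusted p = 0.053 to 0.075). Adjusted over the list alone the counts were the same. Of the 13, ALB, the albumin gene, and SERPINA1 lay under the background at both stages. The camera call at adjusted p = 0.0014 was lost at adjusted p = 0.22 with an estimated correlation.

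All 11 basement membrane genes rose, also adjusted over the list alone. NID2 and NID1, the nidogens that link laminin to collagen IV, rose by 4.42 ± 0.10 and 2.29 ± 0.11, LAMA1, a laminin chain, by 1.60 ± 0.10 and COL4A2 by 1.17 ± 0.07. Camera gave adjusted p = 3.8e-05, and adjusted p = 0.059 with an estimated correlation. Of 8 extraembryonic endoderm genes 7 rose and 1, SOX7, fell by 1.12 ± 0.11, with the same counts adjusted over the list alone. THBD (thrombomodulin) rose by 3.62 ± 0.12 and DAB2 by 1.89 ± 0.07 (adjusted p = 0.018, adjusted p = 0.20 with an estimated correlation and adjusted p = 0.073 with the filter on low values).

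Of 9 Nodal and Activin genes 7 fell, though ACVR1B and SMAD7 lost their calls without any 1 of 5 arrays (adjusted p = 0.060 to 0.13 and 0.059 to 0.084). CER1, given below with the definitive endoderm list, is among the 7. LEFTY1 fell by 1.97 ± 0.09 and NODAL by 0.48 ± 0.07, and FOXH1 rose by 0.40 ± 0.07, though it stood at -0.24 without the probe sets shared between transcripts (adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation and adjusted p = 0.057 with the filter on low values). Of 13 primitive streak genes 8 fell, among them FGF17 by 3.17 ± 0.14 and GSC by 2.50 ± 0.20, and 1, TBXT, rose by 1.21 ± 0.08 (adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation). Of 15 pluripotency genes 11 fell, NANOG by 0.95 ± 0.11 and SOX2 by 1.49 ± 0.13 among them, and 1, GDF3, a TGF-beta family ligand, rose by 2.57 ± 0.11 (adjusted p = 0.0016, and adjusted p = 0.17 with an estimated correlation). DPPA2, among the 11, lost its call without any 1 of 4 arrays (adjusted p = 0.061 to 0.13). These counts did not move when adjusted over the list alone.

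In the definitive endoderm list 7 genes fell and 2 rose, also adjusted over the list alone. CER1 changed by -5.24 ± 0.25, HHEX, a transcription factor of the anterior endoderm, by -3.03 ± 0.20 and KIT, a receptor tyrosine kinase, by -1.80 ± 0.11, while CD177 rose by 1.11 ± 0.08 and GATA4 by 0.34 ± 0.10, a call lost without stage 1 replicate 3 (0.29, adjusted p = 0.068) or stage 2 replicate 3 (0.28, adjusted p = 0.057). FOXA2 and GATA6 changed by 0.06 ± 0.10 and 0.15 ± 0.10 and did not pass (camera, adjusted p = 0.019, adjusted p = 0.22 with an estimated correlation, adjusted p = 0.073 with the filter on low values and adjusted p = 0.069 without shared probe sets).

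The other lists did not pass camera. Of 13 Hedgehog genes, those of the inhibited pathway, 7 rose and 4 fell (adjusted p = 0.81): GLI1 fell at least 3.15-fold to background, GLI2 fell by 0.64 ± 0.06, PTCH1 rose by 0.24 ± 0.06, HHIP by 2.33 ± 0.11 and the ligand IHH by 2.81 ± 0.18. Of 14 genes of FGF receptors and feedback 7 rose and 4 fell (adjusted p = 0.76). FGFR1 and FGFR4 rose by 2.10 ± 0.07 and 2.03 ± 0.08, and DUSP6, a phosphatase induced by FGF signals, by 1.07 ± 0.07. Of 12 Wnt targets 6 rose and 3 fell (adjusted p = 0.32), with LEF1 up by 4.37 ± 0.26, NKD1 by 2.84 ± 0.12 and DKK1 down, having fallen by 1.43 ± 0.10. Of 11 foregut genes 4 rose and 2 fell (adjusted p = 0.63), with rises of ISL1, a transcription factor of the pancreas and heart fields (2.98 ± 0.14), and of RFX6, needed for islet development (at least 2.40-fold), while PDX1, the pancreatic master regulator, changed by 0.13 ± 0.10 and did not pass. Of 6 hindgut genes 3 rose and 0 fell (adjusted p = 0.32), CDX2 by 1.96 ± 0.17, HOXB9 by 1.18 ± 0.13 and HOXD13 by 0.38 ± 0.14, a call lost without any 1 of 4 arrays (0.26 to 0.39, adjusted p = 0.084 to 0.14). Of 12 epithelial genes 9 rose and 1 fell (adjusted p = 0.060), CLDN3 among the 9 standing at -0.067 when all its probe sets were averaged, and of 9 mesenchymal genes 5 rose and 2 fell (adjusted p = 0.32).

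No list of markers of other cell types passed camera at this step, and single members moved both ways. Fry called each of them, the neural list down (adjusted p = 0.0065) and the others up. LUM, a fibroblast proteoglycan, rose at least 7.44-fold and POSTN at least 15.6-fold, in a fibroblast list with 4 rises and 3 falls among 10 genes (adjusted p = 0.63). COL1A1 rose by 0.67 ± 0.08 and COL1A2 fell by 0.68 ± 0.09. TEK, an endothelial receptor, rose by 2.95 ± 0.08 PECAM1 by 2.13 ± 0.29 and CDH5 by 0.47 ± 0.11, while KDR, another endothelial receptor, fell by 1.27 ± 0.09 (7 rises and 1 fall among 11 genes, adjusted p = 0.11). GATA3 and GATA2, transcription factors of the trophoblast list, rose by 2.27 ± 0.10 and 3.54 ± 0.09 (4 rises and 1 fall among 9 genes, adjusted p = 0.32), and HAND1, a mesoderm and heart factor, at least 21.3-fold (5 rises and 2 falls among 10 genes, adjusted p = 0.32). Of 10 neural genes 2 rose and 3 fell (adjusted p = 0.63), and of 21 cell cycle genes 8 rose and 8 fell (adjusted p = 0.44). Adjusted over the list alone 8 endothelial, 6 mesoderm and 9 cell cycle genes rose, and the other counts of these lists held. When all probe sets of a gene were averaged, CDK1, a cell cycle gene counted as rising, stood at -0.18 and PAX3, a mesoderm gene counted as falling, at 0.042. ERG, counted as rising within the background, stood at -0.11 without shared probe sets.

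**Figure D3:**
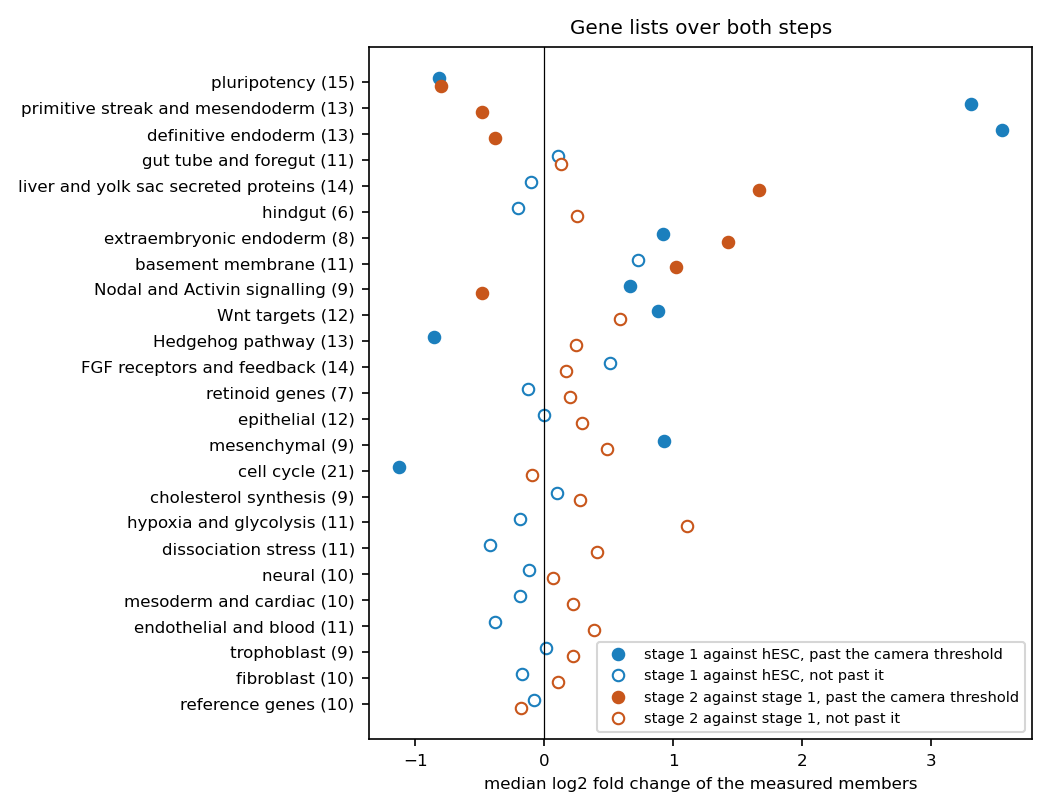
Median log2 fold change of the measured members (their number in parentheses) of each of the 25 gene lists, for stage 1 against hESC and stage 2 against stage 1. Filled points passed limma's camera test with the preset correlation, 9 lists at the earlier step and 7 at the later one, of which 3 and 0 pass with an estimated correlation. Definitive endoderm has the highest median at stage 1 (3.55) and secreted liver and yolk sac proteins at stage 2 (1.66).

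The largest rises outside the lists were those of PAGE4 (at least 220-fold), RSPO3, an enhancer of Wnt signalling (at least 147-fold), HMOX1, the haem-degrading oxygenase (at least 142-fold), HPGD, which inactivates prostaglandins (at least 108-fold), GASK1B (at least 71.2-fold), BMP6, a bone morphogenetic protein (at least 66.1-fold), and HABP2, a plasma protease (at least 41.2-fold). KCNJ16, a potassium channel, rose by 6.22 ± 0.19 and KLHL14, from a stage 1 mean of 5.33 (log2), by 5.96 ± 0.17. CD48, a surface glycoprotein of leukocytes, fell at least 49.6-fold, IL18R1, an interleukin receptor chain, at least 16.9-fold and CFAP95-DT at least 13.4-fold. SHISA2, an inhibitor of Wnt and FGF receptors, fell by 5.60 ± 0.13, FREM1, an extracellular matrix protein, by 5.38 ± 0.12, MFAP4, a microfibril protein, by 5.35 ± 0.16, SAMD3 by 5.24 ± 0.16, LINC01467 by 4.83 ± 0.18 and UPK1B, a uroplakin, by 4.54 ± 0.10. In all, limma called 6296 rises and 4661 falls at adjusted p under 0.05, with 1725 and 1027 of at least 2-fold. The arrays of both stages did not overlap for 59.9% of genes, against 10% by chance, and 1081 of 6557 called genes with several probe sets had probe sets called in opposite directions.

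Stage 2 against hESC spans both steps, but the line and the sort differ in it too, so its changes are not those of differentiation alone. CST1, a cystatin, rose at least 443-fold, DNAJC15, a mitochondrial co-chaperone, by 8.19 ± 0.08 and APOA2 by 8.53 ± 0.11. GATA6-AS1 rose at least 195-fold and SOX17 at least 156-fold. SOX2 fell by 6.61 ± 0.13, IDO1, a tryptophan-degrading enzyme, at least 70.6-fold, COL14A1, a fibril-associated collagen, at least 23.7-fold, CNMD at least 89.4-fold and JAKMIP2-AS1 at least 70.4-fold. All 11 basement membrane genes rose, though LAMC1 lost its call without any 1 of 5 arrays (0.22 to 0.29, adjusted p = 0.054 to 0.080; camera, adjusted p = 3.0e-06, and adjusted p = 0.029 with an estimated correlation), and all 21 cell cycle genes fell (adjusted p = 5.2e-09, and adjusted p = 0.029 with an estimated correlation), the counts being the same adjusted over the list alone.

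Another 10 lists passed camera and were lost with an estimated correlation. Of the pluripotency genes 13 of 15 fell and GDF3 rose (adjusted p = 3.7e-05, and adjusted p = 0.064 with an estimated correlation). Definitive endoderm had 10 rises, that of FOXA3 lost without any 1 of 2 arrays (adjusted p = 0.056 to 0.085), and 1 fall, HHEX, lost without any 1 of the hESC arrays (adjusted p = 0.090 to 0.11), among 13 genes (adjusted p = 2.2e-05, and adjusted p = 0.066 with an estimated correlation). Wnt targets had 9 rises and 1 fall, AXIN2, among 12 (adjusted p = 0.00019, and adjusted p = 0.11 with an estimated correlation). Mesenchymal genes had 8 rises among 9, TWIST1 by 3.50 ± 0.13 and SNAI2 by 3.61 ± 0.16 (adjusted p = 0.00018, and adjusted p = 0.11 with an estimated correlation). Secreted liver and yolk sac proteins had 11 rises and 1 fall, AFP, among 14, with the calls of ALB and SERPINA1, within the background, lost without any 1 of 4 and of 3 arrays (adjusted p = 0.054 to 0.11 and 0.055 to 0.067; list, adjusted p = 0.0016, and adjusted p = 0.21 with an estimated correlation). Extraembryonic endoderm had 7 rises and 1 fall, SOX7, among 8 (adjusted p = 0.00070, and adjusted p = 0.092 with an estimated correlation). Nodal and Activin genes had 6 rises among 9 (adjusted p = 0.0077, adjusted p = 0.11 with an estimated correlation and adjusted p = 0.084 with all probe sets averaged), primitive streak genes 8 rises and 2 falls among 13 (adjusted p = 0.018, and adjusted p = 0.13 with an estimated correlation) and FGF receptors and feedback 10 rises and 3 falls among 14 (adjusted p = 0.018, and adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis had 7 rises among 9 (adjusted p = 0.024, adjusted p = 0.43 with an estimated correlation, adjusted p = 0.051 with the filter on low values, adjusted p = 0.13 with all probe sets averaged and adjusted p = 0.31 without shared ones). IDI1, among the 7, stood at -0.0061 when all its probe sets were averaged and at -0.70 without the shared ones, and SREBF2 lost its call without any 1 of 3 arrays (adjusted p = 0.071 to 0.090). Those counts stayed the same adjusted over the list alone. Over all genes limma called 5956 rises and 6032 falls at adjusted p under 0.05, with 2018 and 1903 of at least 2-fold. Arrays did not overlap for 64.9% of genes, against 10% by chance, and 1046 of 7130 called genes with several probe sets had probe sets called in opposite directions.

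Over both steps, at adjusted p under 0.05 and at least 2-fold each, 437 genes rose and then fell, 621 fell and then rose, 136 rose at both steps and 99 fell at both. Independent lists of these sizes would give 75.7, 178, 127 and 105.7 genes. That expectation leaves out that both steps hold the stage 1 level, with opposite signs. Levels unrelated between the groups would thus also give more reversals than independent lists. Over 20 simulations with no effect, all classes together held at most 4 genes at an unadjusted p under 0.05 and at least 2-fold at both steps. The log2 fold changes of the steps covaried across genes with -0.29, against -0.0055 simulated from the shared stage 1 arrays, a difference of -0.28. Their correlation was -0.35, against -0.40 in the simulation, which drew the noise of each array independently. Among genes that rose and then fell were CD48, FREM1, CER1, MFAP4, IL18R1 and CFAP95-DT. TFAP2A, a transcription factor of ectoderm and trophoblast, fell at least 15.1-fold and then rose at least 23.4-fold, and HPGD, PCDH8, COL12A1, LAYN and TAFA4 took the same course. RELN, the gene of reelin, rose at least 11.0-fold and then by 3.94 ± 0.18, and FOXQ1, a forkhead factor, by 4.19 ± 0.13 and 2.53 ± 0.13, with CST1, SEZ6L and ALPK2 on the same course. MSX2, also called as rising at both steps, stood at -0.11 at stage 1 without the probe sets shared between transcripts. COL14A1 fell by 3.33 ± 0.09 and then at least 2.36-fold, and H1-3, a linker histone gene, changed by -2.46 ± 0.11 and -2.57 ± 0.11, with IDO1, TOX, MT1M and SLC6A15 on the same course.

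**Figure D4:**
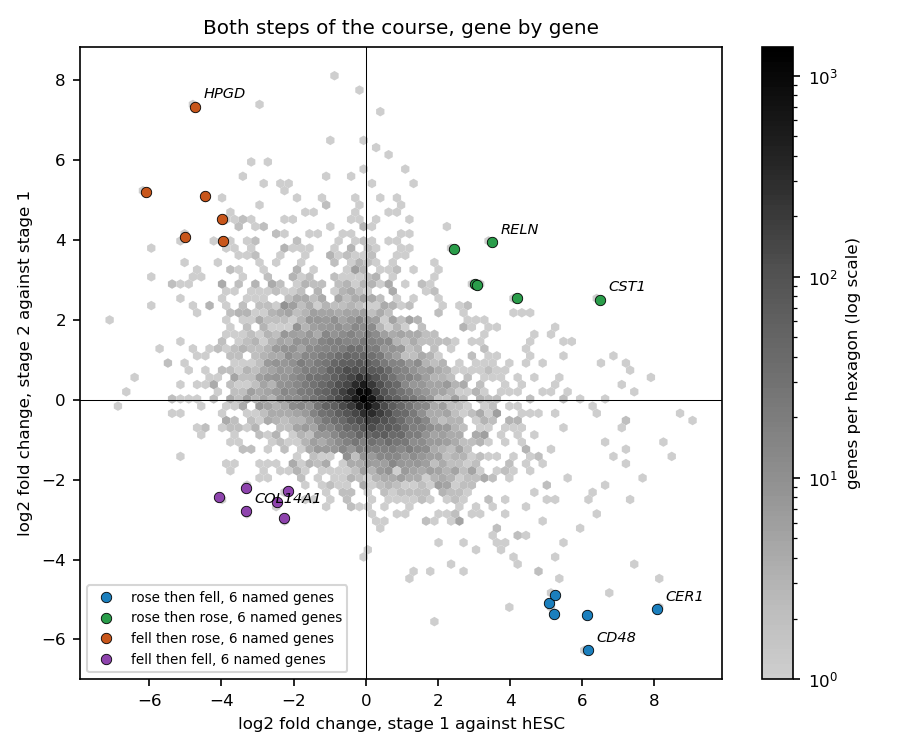
Log2 fold change of stage 2 against stage 1 plotted over that of stage 1 against hESC for 19775 genes, as counts per hexagon on a log scale, with the 6 genes named for each course as coloured points. More genes reversed between the steps (437 and 621) than continued (136 and 99), which the stage 1 level shared by both steps favours by itself.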

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

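The tests of shared-array noise, weaker 5' coverage, the 3 other cell types (with the choice of their markers) and the brightness of unnamed probe sets were chosen only after the results were seen.

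Data outside the gene comparisons held signals. Of 11721 probe sets that name no gene here, controls aside, 1402 rose at least 2-fold at stage 1 over hESC and 539 fell, and 545 rose and 1099 fell at stage 2 over stage 1. The 18S ribosomal RNA control differed by -2.45 (log2) between stage 2 and hESC. The mean of the hybridization controls was higher at stage 2 than in hESC by 0.56 (log2).

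The 437 genes that rose and then fell, and the 621 that fell and then rose, outnumbered what independent lists give, as did the 638 unnamed probe sets that rose and then fell (131 expected). Both steps hold the stage 1 level with opposite signs, so unrelated levels in the groups would also give such an excess. The excess alone is thus no sign that the steps are linked. Independent noise of the shared stage 1 arrays is argued against for the genes by the covariance of the steps, -0.288 against -0.0055 simulated with no effect. The correlation, -0.35 against -0.40 simulated, does not separate them. A shift common to the stage 1 arrays was not simulated and stays open. For the unnamed probe sets noise was not tested. Scaling between arrays cannot be told apart: the lowest ratio to the expectation under other scalings was 3.48, but these hardly moved the arrays, whose medians were already alike, so they are no test of it. Low brightness is argued against for the unnamed probe sets (rises made up 72.2% of their 2-fold changes at stage 1 and 41.2% in named probe sets of matched brightness, a gap of 31.0 percentage points). Weaker 5' coverage at stage 1 is argued against for genes that fell and then rose, since the beta-actin 3' minus 5' difference changed by -0.78 (log2) from hESC. That of GAPDH moved less, with means of 0.355 in hESC, 0.303 at stage 1 and 0.396 at stage 2. Neither control excludes stronger 5' coverage at stage 1 as a cause for the genes that fell and then rose, which was not tested. Stronger 5' coverage cannot be told apart for those that rose and then fell: 85.5% of 228 showed both moves in another probe set (95% binomial interval 80.3 to 89.8%), but positions on transcripts are not used here, and a response to the change of medium between the stages, and more unprocessed RNA at stage 1 for the unnamed probe sets, may contribute and stay open as untested hypotheses.

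Single markers of other cell types rose at stage 2 over stage 1 in cells gated for SOX17-eGFP, such as LUM and POSTN of fibroblasts, TEK and PECAM1 of endothelium and GATA3 of trophoblast, though none of these 3 lists passed camera. POSTN averaged 8.45 (log2) in hESC, 5.27 at stage 1 and 9.26 at stage 2, so it was not new at stage 2. Fibroblasts as the source of LUM and POSTN are argued against by COL3A1 and DCN alone, low at stage 1, with upper 95% bounds of at most 0.55 (log2). Another member of that list, FBN1, rose from 8.73 to 8.98 on the stage 1 arrays to 10.04 to 10.42 on those of stage 2. The high COL1A1 rose by 0.67, COL1A2 fell by 0.68 and neither decides on a small share. Trophoblast cells cannot be told apart from expression within the gated cells: the highest bound of KRT7, CGA and VGLL1 was 0.64, but VGLL1 rose by 0.38 (a call lost without any 1 of 2 arrays, adjusted p = 0.055 to 0.060), TFAP2C by 2.11 and GATA2 by 3.54, and a small share would hardly show in KRT7. GATA2 stood at 9.48 to 9.59 on the hESC arrays, 5.94 to 6.18 at stage 1 and 9.41 to 9.70 at stage 2. Its rise thus returned to the hESC level. Endothelial cells cannot be told apart either: PECAM1 rose (upper bound 2.79) and so did CDH5, by 0.47, while TIE1 changed by 0.08 and did not pass. Expression of these genes within SOX17-eGFP+ cells may account for them, as a hypothesis, and was not tested.

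In 13 genes, among them SOX17, GATA4, CST1 and ERBB4, the level lay at background in hESC and above 10 (log2) at both stages, and in 5, CNMD, CUZD1, HHLA1, JAKMIP2-AS1 and RHBDL3, the reverse held. Gain or loss of a whole autosome is argued against: the largest median change shared by both stages was 0.11 in size (log2), and no autosome held over 16.7% of these 18 genes. A difference between the lines H9 and hSOX17-2 cannot be told apart from differentiation for them, since no undifferentiated hSOX17-2 arrays are among those analysed. Differentiation itself stays open and was not tested apart from the line.

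Of the 10 splits of the 6 arrays of a comparison, 1 gave as many genes called by limma, the real split. That was 10873 genes for stage 1 against hESC, 10957 for stage 2 against stage 1 and 11988 for stage 2 against hESC. The highest of the other splits gave 0 in each, and 125, 743 and 479 genes at an unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached.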

How the results depend on the processing

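The alternative without probe sets shared between transcripts was chosen after seeing the data. Counts of genes that rose, fell or took each course stayed within 1.5 times under each alternative run, and leaving out single arrays moved stage 1 against hESC to 4186 to 4389 rises and 5678 to 5808 falls. Camera called 9, 7 and 12 lists for stage 1 against hESC, stage 2 against stage 1 and stage 2 against hESC. With an estimated correlation it called 3, 0 and 2, and fry, 22, 25 and 23. Without shared probe sets it called 8, 6 and 11, and 8 at stage 1 with the 2 groups alone. With the filter on low values stage 2 against stage 1 had 4 lists. The lists that lost calls are named in the report. Fry turned the trophoblast list down at stage 1 (adjusted p = 0.0023) and the retinoid list up at stage 2 over stage 1 (adjusted p = 0.0018). For these and the reversals below the cause was not tested.

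With the mean of all probe sets of a gene, log2 changes turned to -0.26 for PDGFRA and 0.026 for PGK1 at stage 1 against hESC, to 0.077 for TF, -0.067 for CLDN3, -0.18 for CDK1, -0.44 for IDI1 and 0.042 for PAX3 at stage 2 against stage 1, and to -0.0061 for IDI1 and 0.13 for TBX5 at stage 2 against hESC. Without shared probe sets they turned to -0.11 for MSX2, -0.056 for AGRN, 0.65 for FGFR2 and 0.033 for B2M at stage 1, to -0.24 for FOXH1, -1.90 for IDI1 and -0.11 for ERG at stage 2 against stage 1, and to -0.70 for IDI1, 0.063 for TIE1 and -0.32 for POSTN at stage 2 against hESC. Under both scaling alternatives, array weights, a fit of the compared groups alone and eBayes with trend no named gene or list member reversed, and 8, 4, 18, 22 and 6 lost their call with quantile normalization, centring, weights, groups alone and trend. The mean of all probe sets cost 31 calls, leaving out shared ones 26, and leaving out single arrays 198 over all such runs.

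With the replicate number as a replicate block, stage 1 against hESC had 4476 rises and 6067 falls, 10 named genes or list members lost their call and none reversed. Same-numbered arrays correlated with r from -0.11 to 0.088 across genes in their deviations from group means, so the numbers are not shown to pair arrays. Signal over background limits the dim genes, whose changes are given as bounds.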

Other observations

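The values without shared probe sets come from an alternative chosen only after the results were seen.

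Genes of sugar metabolism and of the response to low oxygen moved both ways. At stage 1 EGLN3, an oxygen sensor, fell by 3.49 ± 0.11 and SLC2A1, a glucose transporter, by 1.55 ± 0.07 on the log2 scale (SE, n = 3). At stage 2 EGLN3 rose by 3.17 ± 0.11, SLC2A1 by 2.53 ± 0.07 and PFKFB4 by 1.54 ± 0.15. PDK1, an inhibitory kinase of pyruvate dehydrogenase, went the other way, with 0.90 ± 0.09 and then -2.15 ± 0.09. Of 11 genes of the hypoxia and glycolysis list 4 rose and 6 fell at stage 1 (limma's camera, adjusted p = 0.91) and 7 rose and 2 fell at stage 2 over stage 1 (adjusted p = 0.20), 3 having fallen there adjusted over the list alone. PGK1, counted as falling at stage 1, stood at 0.026 when all its probe sets were averaged. The retinoid test at stage 2 points down while the median and mean of the list are above 0. Of 7 retinoid genes 2 rose and 1 fell at stage 1 (adjusted p = 0.83) and 3 rose and 2 fell at stage 2 (adjusted p = 0.86). CYP26A1, which degrades retinoic acid, rose by 2.35 ± 0.07 at stage 1, and DHRS3, a retinal reductase, fell by 3.76 ± 0.08 and then rose by 2.26 ± 0.08.

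Of 11 dissociation stress genes 3 rose and 8 fell at stage 1 (adjusted p = 0.50) and 7 rose at stage 2 (adjusted p = 0.12), 8 adjusted over the list alone. The immediate early genes FOS and EGR1 fell by 2.28 ± 0.17 and 1.03 ± 0.09 at stage 1, though those cells were sorted, and IER3 rose by 2.75 ± 0.08. Cholesterol synthesis had 4 rises among 9 genes at stage 1 (adjusted p = 0.17) and 6 at stage 2 (adjusted p = 0.32), with HMGCS1 up by 0.61 ± 0.09 and LSS by 0.64 ± 0.09 at the later step. IDI1, among the 6, stood at -0.44 when all its probe sets were averaged and at -1.90 without the shared ones. Of 10 reference genes 1 rose and 4 fell at stage 1 (adjusted p = 0.53), and 1 rose and 5 fell at stage 2 over stage 1 (adjusted p = 0.14). ACTB changed by -0.04 ± 0.06 and -0.08 ± 0.06. B2M, counted as falling at stage 1, stood at 0.033 without shared probe sets, while HPRT1 fell by 1.55 ± 0.12 and then by 1.04 ± 0.12. With adjustment within the list, 2 reference genes rose at stage 1 and 6 fell at stage 2.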
